A study of Caenorhabditis elegans with 2 samples.

How the data were processed

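Chromatin immunoprecipitation with sequencing was done on whole L4 hermaphrodites of Caenorhabditis elegans strain OP248, which carries MES-2 with a C-terminal GFP-FLAG tag, per the labels. The antibody was against GFP and the chromatin was sheared by sonication, per the labels. The 2 samples are biological replicates of 1 group, numbered 1 and 2 in the labels. Separate worm cultures are not described beyond that number, so p-values measure spread over peaks, genes or chromosomes, not over animals.

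The authors' deposited files are 8 peak lists in narrowPeak layout, 4 on ce10 and 4 on ce11. Per the submitters' file lists, each build has an unthresholded list per replicate, an unthresholded list from the pooled alignments of both replicates, and a list thresholded by irreproducible discovery rate (IDR), all called against a control alignment. All 6 unthresholded lists hold exactly 30000 regions. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The authors' signal column holds 1 positive signal value per peak, whose scale and normalization to depth are not given in the sources used here, so signals were used only to rank and describe peaks within a list. The deposited q column holds −log10 q-values by the layout's definition. In the thresholded ce11 list 4075 of 5501 peaks share the highest −log10 value of 3.91, so it was not used for ranking. All 5501 thresholded peaks were found among the 5501 pooled regions of highest signal, so the threshold equals a limit on signal. In 8 cases the same interval is listed again with another summit; these were kept as listed. The lists give no read counts, so depth is unknown, and no interval that needs depth is given. A peak's absence can therefore reflect shallow sequencing.

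The ce11 lists led, since their coordinates fit the reference in hand: chromosome names and lengths were checked against the WBcel235 genome, and all peaks fell inside it. Genes and transcripts came from the Ensembl annotation of WBcel235. No genome of ce10 was used here, and no coordinate was converted. For the ce10 alternatives, which need only chromosome lengths, those of WBcel235 served as the scale. The thresholded list has 5533 peaks on ce10. Positions are 1-based.

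A summit within 500 bp of any annotated protein-coding transcript start made a promoter peak, and a gene with such a summit was called promoter-bound. Where several starts fell in the window, each of their genes was counted. Other summits were classed in the order 5' UTR, coding exon, 3' UTR, intron, non-coding gene or pseudogene, and intergenic, with shares of the summits away from promoters and expected shares from 100 random circular shifts. Shares of peaks or genes have exact Clopper-Pearson 95% intervals, which cover counting error only. For a count of 0, the limit is the share that 3 counts give.

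The comparisons, their tests, the gene lists and the rule for named genes were fixed before the data were examined. Replicate agreement was the share of the strongest N regions of replicate 1 (N being the number of thresholded peaks) that overlap the strongest N of replicate 2, against 1000 circular shifts within chromosomes. The same shifts served promoter share and non-coding classes with at least 20 members. Peak density on X was tested with an exact binomial test, and arms against centres with an exact sign-flip test over 5 autosomes. Medians of signal and GC differences were tested by permutation with 100000 resamples. The rank correlation has a bootstrap interval from 1000 resamples of peaks. Of 23 gene lists, 22 with at least 5 annotated members were tested, namely homeobox genes, other developmental transcription factors, nuclear hormone receptors, neuropeptides, neuronal genes, chemoreceptors, collagens and cuticle genes, sperm genes, germ-line genes, muscle genes, intestinal genes, C-type lectins, F-box, MATH and BTB families, cytoplasmic ribosomal proteins, translation factors, the proteasome, mitochondrial respiration, splicing, histones, chromatin regulators, Wnt, Notch, EGF and TGF-beta signalling, and heat shock proteins; mes-2 and unc-119 were only described. Members were matched by symbol. Genes named in the text are those at the 25 strongest promoter peaks, each named by the nearest start of a gene with a class symbol, the 4 promoter-bound members of highest signal of each list above other genes, the 2 highest of each lower or untested list, and mes-2 and unc-119. For lists that passed neither way, on which the rule is silent, the 2 highest were named too.

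The 62 alternatives planned were a stricter list (the 2750 strongest peaks), a relaxed list (the 17622 pooled regions with −log10 q of at least 2), each replicate alone, windows of 250 and 1000 bp, the ce10 lists, other definitions of overlap, boundaries, backgrounds, gene assignment and flanks. The comparisons of promoter peaks and promoter-bound genes between X and autosomes, and the count over overlapping windows around mes-2, were also added after the data were seen. Another 5 alternatives, chosen after the data were seen, were random shifts for the gene lists, the X without peaks near tRNA genes, promoter share and gene lists without the 40 kb around mes-2, and gene lists without members whose symbol class is not what the list's name says.

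The statistics were tested on simulated data. With summits placed uniformly over the genome in 20 runs, the Fisher comparison of gene lists called 19 of 440 lists, 15 of them the chemoreceptors, and the comparison with shifts called 0 of 440. The shifts assume such placement, so their count does not cover summits that gather at starts. The promoter share passed in 0 of 20 such runs. With 4 lists planted as bound, all 4 were called, and 2 of 18 others. With 60% of the regions shared by construction, the replicate comparison gave 60.4%. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.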

Results

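Sites enriched by precipitation of tagged MES-2 were mapped by chromatin immunoprecipitation and sequencing. The material was whole hermaphrodites of Caenorhabditis elegans at the L4 larval stage. MES-2 is the worm counterpart of Enhancer of zeste, the histone methyltransferase subunit of Polycomb repressive complex 2. The worms, of strain OP248, carried MES-2 with a C-terminal GFP-FLAG tag, and the protein was precipitated with an antibody against GFP. All 2 samples belong to 1 group and are biological replicates 1 and 2 of the same strain and stage. The design thus compares the replicates with each other and the peak positions with the rest of the genome. The authors' thresholded list, made from both replicates, held 5501 peaks on ce11, with a median width of 188 bp. Its signal value, the authors' own height of each peak, ran from 73.5 to 2503 with a median of 140. The lists give no read counts, so the sequencing depth of each replicate is unknown. No control sample was analysed here, so binding by MES-2 cannot be told apart from signal that any immunoprecipitation may give. The 2 replicates are the only measure of experimental error.

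Each of the 25 strongest promoter peaks named below, chosen by pooled signal, was among the 5501 strongest regions of both replicates, with ranks that were close for some genes and far apart for others. The summit at the start of cux-7 was the highest of the thresholded list, and in the replicate lists it ranked 2 in replicate 1 and 4 in replicate 2. The peak upstream of rpl-15, which encodes a protein of the large ribosomal subunit, ranked 11 in replicate 1 and 1 in replicate 2. The peak upstream of rpl-3, another large-subunit gene, ranked 7 and 5. The nurf-1 peak ranked 74 and 10, and the lrpr-1 peak 18 and 66. Of the 5501 strongest regions of replicate 1, 3728 (67.8%) overlapped 1 of the 5501 strongest regions of replicate 2 by at least 1 bp. Random circular shifts of replicate 2 within chromosomes gave 1.88% ± 0.183 (SD of 1000 shifts) and at most 2.42%, and the two-sided permutation p of 0.002 is the smallest that 1000 shifts can give.

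Since both the pooled list and the replicate lists are ranked by the same signal, weak peaks must fall out of the replicates' strongest regions first. Of the thresholded peaks split into 4 equal groups by signal, 98.9% of the highest group, from 249.9 upward, overlapped the 5501 strongest regions of both replicates. The share was 92.9% and 55.7% in the next groups and 11.6% in the group of lowest signal, from 73.5 to 95.4. Of all thresholded peaks, 96.9% overlapped some region of the unthresholded list of replicate 1 and 98.3% one of replicate 2, and 5235 (95.2%) overlapped both. Across those 5235 peaks the replicates' signal values had a Spearman correlation of 0.739, with a bootstrap 95% interval of 0.723 to 0.753, and a Pearson correlation of 0.768 on the log2 scale. Peaks are not independent replicates, so no p is given for these correlations. The summits that the replicates placed in the same peak lay a median of 20 bp apart, and 80.4% of the pairs lay within 50 bp.

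**Figure D1:**
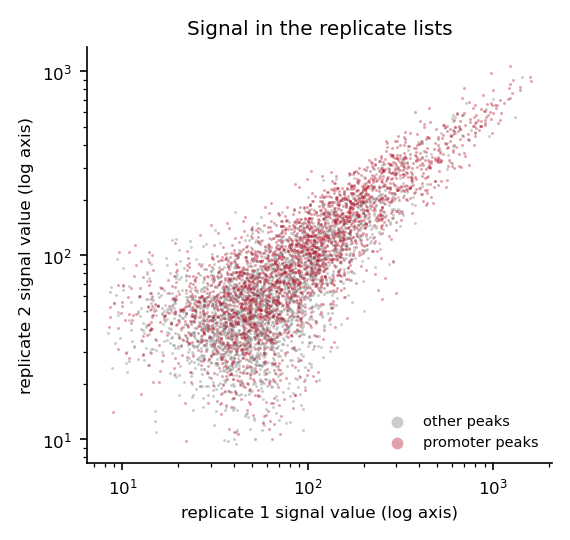
Signal values of the 5235 thresholded peaks that overlap a region in both replicate lists, replicate 1 on the x axis and replicate 2 on the y axis, both on log axes and in the authors' signal units; red points are peaks with a summit within 500 bp of a protein-coding transcript start. The Spearman correlation is 0.739 over these 5235 peaks.

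Among the highest promoter peaks were those of the ribosomal protein genes rpl-15, rpl-3, rpl-35 and rpl-20, beside genes of many other functions, and no test of shared function was made on this set. Taking the 25 strongest peaks with a summit within 500 bp of the start of a protein-coding gene with a class symbol, all 25 summits lay upstream of the nearest such start, at a median distance of 230 bp and between 2 and 452 bp. In the annotation, 22 of these summits lay between genes and 3 inside a transcribed unit. The cux-7 peak covered chromosome III from 7520733 to 7520963 (ce11, as for all positions here). Its summit at 7520847 lay 2 bp upstream of the cux-7 start, with a signal of 2503, and within 500 bp of the start of C07H6.2 as well. The rpl-15 summit lay on chromosome IV at 654929, 353 bp upstream, with a signal of 2315, and the start of K11H12.8 was within the same window. The wbp-4 peak, on chromosome I at 11374451, reached 2200. The rpl-3 peak, on chromosome III at 3867571 and 283 bp upstream, reached 2155. Ribosomal protein genes were joined by rpl-35 at 1652 and rpl-20 at 1460.

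The other genes of this set had signals between 1434 and 2037. Protein folding and turnover were represented by pinn-1, a peptidyl-prolyl isomerase (2037), cdc-48.1, an AAA ATPase that extracts ubiquitinated proteins (1928), tasp-1, a threonine aspartase (1793), cyn-10, a cyclophilin (1633), and ahsa-1, an activator of the Hsp90 ATPase (1526). The pinn-1 summit lay in an intron of a neighbouring gene, 392 bp upstream of the pinn-1 start. Gene expression factors included thoc-5 of the THO complex of mRNA export (1800), eif-3.B of translation initiation factor 3 (1712), and gfm-1, the mitochondrial elongation factor G (1438). Mitochondrial factors included mppb-1, a subunit of the processing peptidase (1691), and sco-1, a copper chaperone of cytochrome c oxidase (1565). Chromosome proteins were hcp-6, a condensin subunit whose window also held the start of let-630 (1650), and nurf-1, a subunit of the NURF nucleosome remodeller (1563). The nurf-1 summit lay in an intron of nurf-1, upstream of an internal start, and inside the peak-rich stretch around mes-2 that is described below. The remaining genes were lrpr-1 (1596), sluh-7 (1553), ced-5, an engulfment regulator (1533), lron-10 (1516), dpm-3, a subunit of dolichol-phosphate mannose synthase that shared its summit with rps-23 (1502), bmy-1 (1453) and cnk-1, a scaffold of Ras signalling (1434).

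Peaks lay within 500 bp of protein-coding starts, on either side, more often than random placement gives, and few lay in coding sequence. Of the 5501 summits, 2878 (52.3%, exact 95% interval 50.99 to 53.65%) were within 500 bp of a protein-coding transcript start, called promoter peaks here. Random circular shifts gave 22.9% ± 0.603 (SD), so the share was 2.29 times the random one (two-sided permutation p = 0.002, the smallest that 1000 shifts can give). Among the 2623 summits away from promoters, 6.14% lay in coding exons, against 23.2% ± 0.782 (SD of 100 shifts) for shifted summits away from promoters, 48.99% were intergenic, against 32.99% ± 0.827, and 32.6% lay in introns, against 35.3% ± 0.918. These shares, chosen after the data were seen, were not tested. In all, 3311 of 19973 protein-coding genes (16.6%) had a summit within 500 bp of a start and are called promoter-bound below. The term refers to the position of a summit only.

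Promoter peaks were also higher. Their median signal was 177.9, against 115.8 for the 2623 other peaks, a difference of 62.1 (permutation test over peaks with 100000 resamples, two-sided, p = 1e-05, the smallest possible). With the peaks split into 10 equal groups by signal, 81.7% of the highest group and 34.5% of the lowest were promoter peaks. With the relaxed list of 17622 pooled regions the difference fell to 17.4, and in the replicate lists, whose signal is on another scale, it was 29.6 in replicate 2 and 29.9 in replicate 1.

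**Figure D2:**
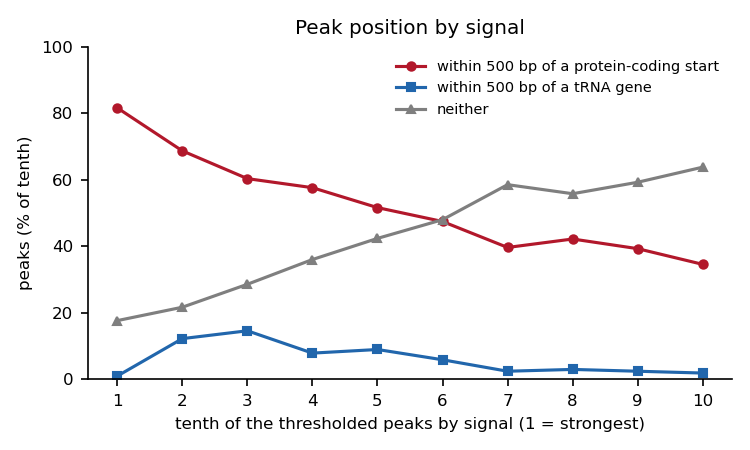
Share of thresholded peaks, in percent of each of 10 equal groups by signal (x axis, 1 the strongest), with a summit within 500 bp of a protein-coding start, within 500 bp of a tRNA gene, or near neither. Promoter peaks fall from 81.7% in the strongest group to 34.5% in the weakest, and peaks near tRNA genes are most frequent in group 3, at 14.5%.

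Genes for ribosomes, translation, protein turnover, splicing and respiration were promoter-bound more often than other genes, and chemoreceptors almost never. Each of 22 gene lists was compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists (adjusted p below), and 14 passed 0.05, 7 of them higher and 7 lower. Since list members can share chromosomes and clusters, the bound members were also compared with random circular shifts of the summits, a comparison chosen after the data were seen. By that comparison 14 lists passed as well, 13 higher and 1 lower.

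Of 80 genes for cytoplasmic ribosomal proteins, 69 (86.3%, exact 95% interval 76.7 to 92.9%) were promoter-bound, with an odds ratio of 32.2 and an adjusted p of 1.3e-41. Shifted summits gave 4.68 ± 2.08 (SD) bound members. The size of the difference depends on the window: the odds ratio fell to 2.63 with a 250 bp window, the lowest of the 7 higher lists there (proteasome 10.9), and to 7.19 with each summit counted only for its nearest start, still past the threshold in both. Besides rpl-15 and rpl-3, the strongest were rpl-35 (1652) and rps-23 of the small subunit (1502). Of 31 proteasome genes 25 (80.6%) were bound (Fisher's exact test, adjusted p = 2.82e-14), against 1.82 ± 1.32 for shifted summits. The strongest were pas-3 (635) and pbs-3 (635) of the core particle, and rpn-3 (626) and rpn-11 (558) of the regulatory particle. Of 62 genes for translation factors and aminoacyl-tRNA synthetases 39 (62.9%) were bound (Fisher's exact test, adjusted p = 2.4e-15), against 4.62 ± 2.06. Besides eif-3.B, the strongest were ears-2, a glutamyl-tRNA synthetase (1424), eif-3.C (1134) and eif-3.E (1003).

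The splicing and mRNA processing list had 40 of 67 genes bound (59.7%, Fisher's exact test, adjusted p = 1.01e-14), against 4.58 ± 2.15 for shifted summits. Its strongest members were cpsf-1 of the polyadenylation complex (1084), mog-4 (1047) and mog-3 (1042), known from the switch of the germ line to oocytes, and snr-1, an Sm protein (733). The respiration list had 39 of 72 genes bound (54.2%, Fisher's exact test, adjusted p = 9.16e-13), against 4.27 ± 2.03, with atp-5 (1247), atp-1 (822) and atp-3 (565) of the ATP synthase and cyc-1 of complex III (646) the strongest. That list also took in 33 hpo and lpd genes, named for other phenotypes, of which 14 were bound, and without them 25 of 39 genes were bound (64.1%, Fisher's exact test, adjusted p = 9.04e-11), a choice made after the data were seen. The heat shock and chaperone list had 33 of 62 genes bound (53.2%, Fisher's exact test, adjusted p = 9.04e-11), against 4.18 ± 2.10, led by hsp-90 (1355), dnj-28 (1192), cct-1 of the chaperonin (976) and dnj-12 (831).

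Regulators of chromatin, the list that holds the Polycomb, trithorax-like and synMuv factors, had 47 of 92 genes bound (51.1%, exact 95% interval 40.4 to 61.7%, adjusted p = 7.71e-14), against 7.07 ± 2.48 for shifted summits. Its strongest members were nurf-1 (1563), mes-2 itself (1416), set-2, a histone H3 lysine methyltransferase of the COMPASS type (1240), and lin-54, a DNA-binding subunit of the DRM complex (1220), whose window also held the start of rpl-12. Without the peaks in the 40 kb around mes-2, a choice made after the data were seen, the odds ratio of this list was 4.88 (Fisher's exact test, adjusted p = 1.71e-12).

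Of the lists that were lower than other genes, only the chemoreceptors were also lower than shifted summits. Of 1311 chemoreceptor genes, 8 (0.610%, exact 95% interval 0.264 to 1.199%) were promoter-bound (adjusted p = 2.96e-91), against 55.8 ± 7.76 for shifted summits (adjusted permutation p = 0.0037). On simulated summits placed uniformly at random, the Fisher comparison called this list in 15 of 20 runs and the shifts in none. Uniform placement is what the shifts assume, so those runs do not show how the shifts behave when summits gather at starts. The strongest bound members were sri-5 (621), whose window also held the start of rsr-1, and srh-16 (559). Of the 8 bound chemoreceptor genes, 4 had a summit that was also within 500 bp of a start outside the list, and so did 140 of the 292 bound members of the 7 higher lists.

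The other 6 lower lists were lower than other genes but did not pass 0.05 against shifted summits, so they are called low only beside the genes outside the list. Neuropeptide genes had 3 of 145 bound, against 8.38 ± 2.87 (adjusted p = 5.93e-08 against other genes and 0.0907, a permutation p, against shifts), led by nlp-4 (366) and flp-23 (236). C-type lectins had 6 of 240 bound, against 12.01 ± 3.72 (adjusted p = 6.72e-12 by Fisher's exact test and 0.134 by permutation), led by clec-57 (247) and clec-126 (163). The clec-126 peak overlapped a region of replicate 2 but none of replicate 1. F-box, MATH and BTB family genes had 21 of 450 bound, against 25.4 ± 6.09 (2.82e-14 and 0.613), led by fbxl-2 (857) and sdz-1 (719). The sdz-1 gene was among 33 members whose symbol class is not what the list's name says. Without these, a choice made after the data were seen, 20 of 417 genes were bound (Fisher's exact test, adjusted p = 4.85e-13). Homeobox genes, which pattern the body and specify neurons, had 6 of 99 bound, against 7.03 ± 2.499 (0.00422 and 0.897), led by ceh-38 (676) and duxl-1 (225). Collagen and cuticle genes had 13 of 225 bound, against 12.2 ± 3.38 (2.46e-06 and 0.897), led by col-71 (1312) and col-2 (627). Sperm genes had 7 of 109 bound, against 6.03 ± 2.38 (0.00422 and 0.866), led by spe-48 (611) and spe-39 (556). Of these leading genes, nlp-4, sdz-1, ceh-38, col-71, col-2, spe-48 and spe-39 had a summit that was also within 500 bp of another gene's start. The calls against other genes were lost for homeobox genes with a 250 bp window, for sperm genes in the 2750 strongest peaks, and for collagens in the relaxed list (odds ratios 0.416, 0.538 and 0.907).

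The 8 lists that did not pass the threshold against other genes were bound in 13.3 to 23.8% of their members. They were other developmental transcription factors with 22 of 147 bound, led by nfi-1 (534) and ztf-7 (441), nuclear hormone receptors with 40 of 274, led by nhr-47 (445) and nhr-58 (255.0), and neuronal genes with 10 of 62, led by unc-16 (300.0) and snb-1 (217). Germ-line genes had 25 of 122 bound, led by atx-2 (841) and spn-4 (556), muscle genes 10 of 61, led by unc-60 (256) and act-2 (254), and intestinal genes 13 of 98, led by gut-2 (397) and cpr-4 (114). Histone genes had 20 of 84 bound, led by the H2A variant htz-1 (695) and his-37 (640). Wnt, Notch, EGF and TGF-beta signalling genes had 13 of 65 bound, led by mig-5 (976) and adm-4 (867). The mig-5 summit was also that of cct-1 in the heat shock list, and the spn-4 summit that of spe-39 in the sperm list. The 20 bound histone genes had 13 distinct summits between them. Since summits in general gather at starts, shifts give fewer bound genes than the 16.6% of all protein-coding genes, so a list bound no more often than other genes can still lie above shifts. Against shifted summits, 6 of these 8 were higher, all but the neuronal list (adjusted permutation p = 0.0907) and the muscle list (0.127).

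**Figure D3:**
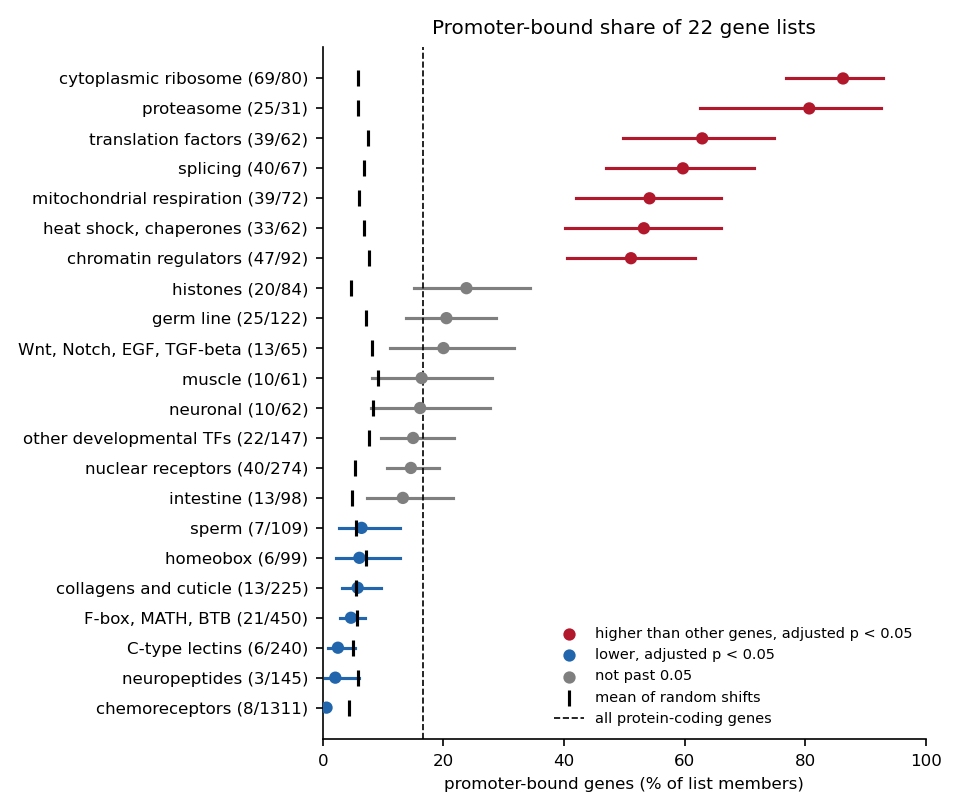
Promoter-bound genes as a percentage of the members of each of 22 gene lists, with bound and total members beside the name, exact 95% binomial intervals as lines, the mean of 1000 random shifts as black ticks, and 16.6% of all protein-coding genes as the dashed line. Ribosomal protein genes lie highest at 86.3%, and chemoreceptors lowest at 0.610%.

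Genes for tRNAs stood out among the non-coding classes. Of 612 tRNA genes, 364 (59.5%, exact 95% interval 55.5 to 63.4%) had a summit within 500 bp, 10.7 times the 5.54% ± 1.04 (SD) of shifted summits. Genes for snoRNAs followed with 133 of 346 (38.4% against 6.14% ± 1.3004), snRNAs with 37 genes (28.7% against 5.33% ± 2.20), lincRNAs with 45 of 194 (23.2% against 10.7% ± 2.20) and miRNAs with 57 of 261 (21.8% against 5.76% ± 1.74). Other annotated ncRNAs had 1155 of 7764 (14.9% against 5.82% ± 0.379). The shifts do not keep the gathering of summits at protein-coding starts, and distance from such starts was examined for tRNA genes only. For the other classes, nearness to protein-coding starts was thus not allowed for. Pseudogenes were lower than shifted summits, with 88 of 2128 (4.14% against 10.3% ± 0.807), and so were piRNA genes, with 108 of 15363 (0.703% against 4.29% ± 0.789).

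In each of these 8 classes the adjusted permutation p was 0.0025, from the smallest p that 1000 two-sided shifts can give. Antisense RNAs, with 15 of 100 (adjusted permutation p = 0.091), and rRNA genes did not differ from shifted summits. Of 20 rRNA genes, 0 had a summit nearby, which allows a share of up to 15%, against 6.07% ± 6.48 for shifted summits. The 328 summits near tRNA genes made up 5.96% of the thresholded peaks, and 249 of them were not promoter peaks. Those 249 had a median signal of 211, against 178 for promoter peaks away from tRNA genes and 111 for the 2374 peaks near neither. Of the 10 groups by signal, group 1, the strongest, had 0.907% of its peaks near a tRNA gene, and group 3 had 14.5%. The tRNA genes include identical copies, between which reads cannot be told apart.

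The X chromosome carried about as many peaks per length as the autosomes, but fewer of them at promoters. MES-2 is needed to keep the X silent in the germ line, which makes this the comparison of interest. The X held 931 peaks (16.9% of all, exact 95% interval 15.9 to 17.9%), or 52.5 per Mb against 55.4 per Mb on the autosomes. The ratio was 0.949, which did not differ from an even spread by length (exact binomial test, two-sided, p = 0.152). Among autosomes the density ran from 36.9 per Mb on V to 78.8 on III, so the X lay inside the range of the autosomes, and a one-sided permutation over 6 chromosomes cannot go below 0.167. Promoter peaks made up 39.1% of X peaks and 55.01% of autosomal peaks (Fisher's exact odds ratio 0.525, p = 7.99e-19). The X has fewer protein-coding genes for its length, 2731 in 17.7 Mb against 17242 in 82.6 Mb on the autosomes. No random shifts were run for X and autosomes apart, so the comparison of peak shares does not allow for that. Promoter-bound genes made up 13.5% of 2731 genes on X and 17.1% of 17242 on the autosomes (Fisher's exact odds ratio 0.759, p = 2.45e-06), but single autosomes ran from 10.3% on V to 26.4% on III, so the X lay inside their range here too. Both of these tests were added after the data were seen.

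Of X peaks, 142 (15.3%) lay near a tRNA gene, against 4.07% of autosomal peaks, and the X carries 45.1% of all tRNA genes. The median signal was 139 on X and 140 on the autosomes, a difference of -1.09 (permutation test over peaks, two-sided, p = 0.824). The density ratio turned to 1.29 (exact binomial p = 9.33e-12) when the expected share was taken from protein-coding genes instead of length, and to 1.02 (p = 0.525) in replicate 2 alone. In the relaxed list the density ratio passed the threshold at 0.927 (exact binomial p = 0.000175), and the difference in signal turned to 1.86 (permutation p = 0.0105). Without the peaks near tRNA genes, a choice made after the data were seen, the density ratio was 0.839 (exact binomial p = 3.63e-06).

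Peaks were denser in the centres of the autosomes than in the arms. With each autosome cut into a centre and arms around it, the centre being 1 of 3 equal parts, the arms held 0.726 times as many summits per Mb as the centres, with a mean log2 ratio of -0.46 ± 0.13 (SD, n = 5 autosomes). All 5 autosomes were lower in the arms, from -0.26 on IV to -0.62 on V. The exact sign-flip test over 5 autosomes gave p = 0.0625, two-sided, the smallest it can give, so this design cannot pass 0.05. Chromosome III had 70.6 summits per Mb in its arms and 95.1 in its centre, and chromosome V 31.3 and 48.2. Counted per protein-coding gene instead of per Mb, the ratio was 0.893 with a log2 mean of -0.14 ± 0.26 (SD, n = 5, exact p = 0.375), so on that scale the autosomes did not all lie on the same side.

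**Figure D4:**
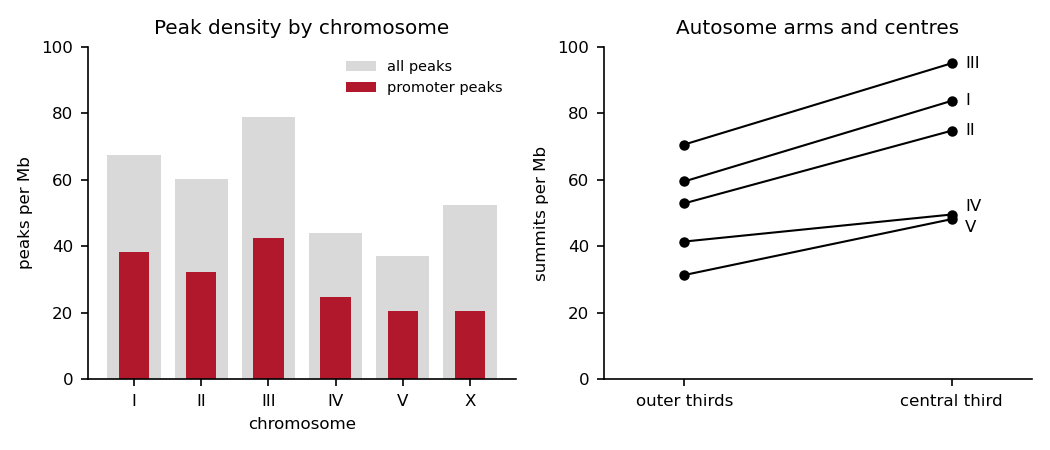
Left, thresholded peaks per Mb on each chromosome as grey bars and promoter peaks as narrower red bars; right, summits per Mb in the arms and the centre of each autosome, joined by a line. Chromosome III is densest at 78.8 per Mb and V sparsest at 36.9, and every autosome is denser in its centre.

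Summits were richer in G and C than their flanks and held GA repeats and a shared CG-containing word. The 100 bp to each side of summits had a GC content of 43.05% ± 6.57 (SD, n = 5501 summits), against 36.4% ± 5.52 in windows centred 500 bp away on each side, a difference of 6.61 percentage points (sign-flip permutation test over peaks, two-sided, p = 1e-05, the smallest possible). The difference was 4.47 ± 8.47 (SD) points at promoter peaks, 8.81 ± 8.31 at peaks near neither a promoter nor a tRNA gene, and 10.3 ± 6.95 at tRNA genes away from promoters. In a narrower window, 50 bp to each side, it was 10.5 points. Of 2080 words of 6 bases, 1578 differed between summits and flanks (Fisher's exact test, Benjamini-Hochberg adjusted p below 0.05), 873 of them more frequent at summits. Of those 873, 546 had 4 or more G or C, and of the 705 less frequent words 493 had 2 or fewer. The flanks were not matched for GC, so these counts cannot be separated from the GC difference. The word GAGAGA stood in 37.8% of summit windows and 11.8% of flanks, 3.21 times as often. The word ACGCAG stood in 21.8% and 4.61%, 4.73 times as often, and CGTCTC in 24.6% and 6.86%, 3.58 times as often. Among AT-rich words, AAAATT stood in 39.9% of summit windows and 63.2% of flanks.

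The tagged gene itself stood in one of the stretches of the genome richest in peaks. The mes-2 gene lies on chromosome II from 14383973 to 14388454, and the peak at its promoter, with a summit at 14383845, had a signal of 1416 and ranked 46 in the thresholded list, 80 in replicate 1 and 15 in replicate 2. The 40 kb centred on the gene, 14366214 to 14406213, held 17 thresholded summits, against a median of 2 and a maximum of 16 over 2503 windows of that size side by side. Among 99955 overlapping windows, counted after the data were seen, 35 held as many. Of the 17 summits, 4 lay away from promoters. Most of the 17 lay inside the nurf-1 gene, from 14390713 to 14407911, where a summit near an internal start of nurf-1 counts as a promoter peak. In each unthresholded replicate list the same 40 kb held 37 summits, a number reached by 0.839% of windows in replicate 1 and 0.959% in replicate 2. By contrast unc-119, a rescue marker widely used in making worm transgenes, on chromosome III from 10902641 to 10908935, had no summit at its promoter. Its strongest nearby peak, with a summit at 10903419 inside the gene, had a signal of 74.1 and ranked 5440. The 40 kb around unc-119 held 2 thresholded summits, the median of all windows.

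**Figure D5:**
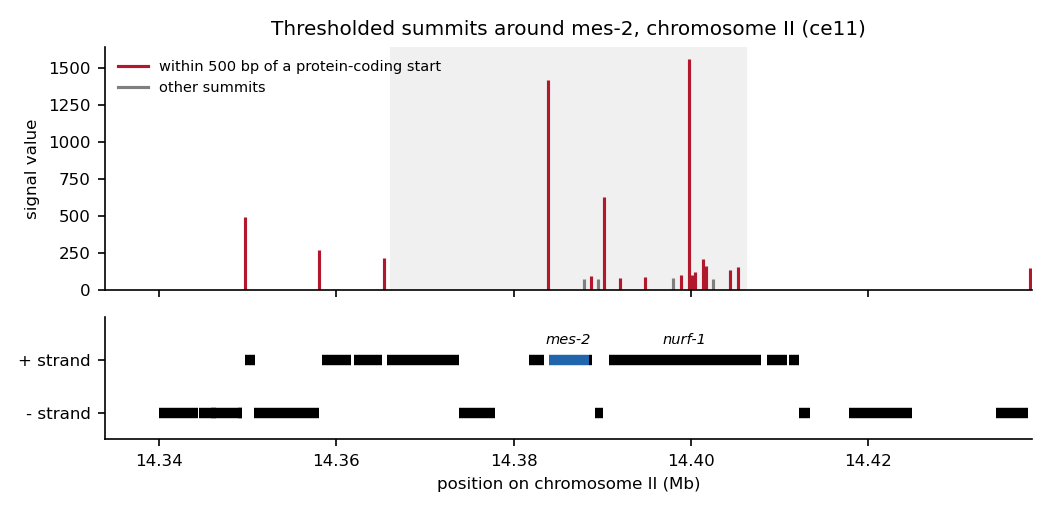
Thresholded summits within 50 kb of mes-2 on chromosome II (x axis, position in Mb on ce11), with height giving the authors' signal value, red for summits within 500 bp of a protein-coding start and grey for the others, above the protein-coding genes of each strand; the shaded part is the 40 kb centred on mes-2. The shaded part holds 17 summits, the strongest at nurf-1 (1563) and mes-2 (1416).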

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

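Of the alternatives in this part, the tests chosen only after the data were seen were the X chromosome without tRNA peaks, the gene lists against shifts, the lists without mismatched members, and promoter share and lists without the mes-2 region. Replicate overlap (52.4 to 76.2%), replicate correlation (0.726 to 0.751), promoter share (36.7 to 65.8%), tRNA genes (44.0 to 65.5%), signal of promoter peaks (17.4 to 58.5), summit GC (5.67 to 10.5 percentage points) and arms against centres (0.653 to 0.893, where the exact test cannot pass 0.05) kept their direction and their side of the threshold in the alternatives run. The ratio of X to autosomes, 0.949 and not past the threshold, passed it in the relaxed list (0.927) and without peaks near tRNA genes (0.839, by leaving out 15.3% of X and 4.07% of autosomal peaks). It lay above 1 with the share of protein-coding genes as expectation (1.29), and from 0.948 to 1.02 without replicate 2 or without replicate 1; the cause was not tested. The signal of X peaks minus autosomal peaks turned to 1.86 in the relaxed list (permutation p = 0.0105), and the cause was not tested. The number of gene lists past the threshold was 14 to 16, and each alternative fixed beforehand kept 13 or 14 of the 14 calls. Lists that passed neither way changed side as follows, none of them past the threshold against other genes, and the cause was not tested. In the relaxed list the odds ratios were 1.31 for other developmental factors, 1.65 for neuronal, 1.58 for muscle and 1.15 for intestinal genes. Without replicate 1 or without replicate 2 that of other developmental factors ranged from 0.807 to 1.12. With a 250 bp window Wnt, Notch, EGF and TGF-beta genes had 0.946, and with 1000 bp neuronal genes 1.02 and muscle genes 1.15. Against class-symbol genes only, germ-line genes had 0.978 and Wnt, Notch, EGF and TGF-beta genes 0.948. With each summit counted for its nearest start, other developmental factors had 1.13, nuclear receptors 1.098, neuronal genes 1.23 and muscle genes 1.26. Against random shifts, a different comparison, the ratio of bound members was 1.97 for other developmental factors, 2.73 for nuclear receptors, 2.71 for intestinal genes (these 3 past the threshold), 1.93 for neuronal genes and 1.802 for muscle genes. Collagens and sperm genes, which had passed as lower against other genes, had 1.07 and 1.16 against shifts, not past the threshold. Lists that passed in an alternative only were, by adjusted p of Fisher's exact test, histones as higher without replicate 1 (0.0278), without replicate 2 (0.026) and at 250 bp (0.00469), germ-line genes as higher in the relaxed list (0.0218) and at 1000 bp (0.0265), Wnt, Notch, EGF and TGF-beta genes as higher in the relaxed list (0.0124), nuclear receptors as lower in the stricter list (0.000785), without replicate 2 (0.0295) and against class-symbol genes (0.0123), and intestinal genes as lower in the stricter list (0.000289). For histones the odds ratio was 1.58 in the main comparison. It was 1.02 with members bound by 1 summit counted once and 1.07 by nearest start, neither past the threshold. Of the 78 named genes with a promoter peak, which leaves out unc-119, 77 had a region among the strongest 5501 of both replicates. These genes were chosen as the highest by pooled signal, so their presence there is no independent support. Depth is unknown, so a missing peak can reflect shallow sequencing.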

Other observations

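The tests on head-to-head neighbours, the gene-class scan, the summit positions, the longer words, the odds ratio between tRNA genes of several copies and of 1 copy, the tRNA shares on X and autosomes, and both tests around mes-2 were chosen only after the results were seen. Among 175 gene classes defined by symbol with at least 10 members, 63 passed 0.05 against other genes after Benjamini-Hochberg adjustment (Fisher's exact test), 28 higher and 35 lower. Several higher classes lay outside the fixed lists. Nucleoporin genes (npp) were promoter-bound in 20 of 26 cases (76.9%, adjusted exact p = 5.65e-10), RNA polymerase II subunits (rpb) and cyclin-dependent kinases (cdk) in 9 of 11 each (81.8%, adjusted p = 3.44e-05), vacuolar ATPase subunits (vha) in 13 of 20 (65%, adjusted p = 2.28e-05), vacuolar sorting genes (vps) in 18 of 31 (58.1%, adjusted p = 3.43e-06), and small and large mitochondrial ribosomal proteins (mrps, mrpl) in 16 of 29 and 19 of 41. Integrator subunits (ints) had 7 of 11 bound and TFIID factors (taf) 9 of 17. Among lower classes, neuropeptide receptors (npr) had 0 of 43 bound, cytochrome P450 genes (cyp) 2 of 74 and UDP-glucuronosyltransferases (ugt) 2 of 67. Of the 35 lower classes, 1, the str chemoreceptors with 0 of 193 bound against 7.58 ± 2.84 (SD) for shifted summits, was also lower than random shifts after adjustment. Smaller classes could not pass that comparison even with 0 bound. The srw class had 0 of 109 bound against 4.14 ± 2.19, and npr 0 of 43 against 2.78 ± 1.61 (permutation p before adjustment 0.0599 and 0.126). Not passing against shifts therefore says little about such classes.

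Genes with a neighbour in head-to-head orientation, its start within 1 kb upstream on the other strand, were promoter-bound in 1358 of 3539 cases (38.4%), against 1953 of 16434 other genes (11.9%, Fisher's exact odds ratio 4.62, p = 2.15e-272). Part of this follows from counting, as 1 summit between the starts counts for both genes. Of 2878 promoter summits, 83.1% (exact 95% interval 81.7 to 84.4%) lay upstream of the nearest start, with a median of -138 bp and quartiles at -245 and -39 bp. The 2623 other summits lay a median of 1556 bp from the nearest start, and 211 lay over 5 kb away.

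The words ACGCAG and CGTCTC, the latter on the other strand, overlap in a longer one. The sequence GAGACGCAG, on either strand, stood within 100 bp of 635 of 5501 summits (11.5%, exact 95% interval 10.7 to 12.4%) and in 1.14% of flanking windows, 10.2 times as often. It was similarly frequent at promoter peaks (11.22%) and at peaks near neither promoters nor tRNA genes (12.8%), but stood at 7 of 249 tRNA peaks away from promoters (2.81%, against 2.01% of their flanks, Fisher's exact p = 0.603). On X it stood at 7.63% of summits and in 0.698% of flanks, 10.9 times as often. On the autosomes it stood at 12.3% and 1.23%, 10.1 times as often, so the enrichment over flanks was similar. The repeat GAGAGAGAGA stood at 9.18% of the peaks near neither and in 1.14% of their flanks, 8.07 times as often. At promoter peaks the shares were 3.02% and 0.521%, 5.8 times as often. CACACACACA stood at 7.03% of the peaks near neither and in 1.12% of their flanks, 6.30 times as often. At promoter peaks its shares were 2.36% and 0.382%, 6.18 times as often, so its enrichment over flanks was similar in both.

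The 7 higher lists were pooled because each had passed, so a pooled odds ratio above 1 (9.17, from 292 of 466 members bound) follows from that selection, and only its change within groups of like genes is informative. Within 10 groups of GC content around starts the Mantel-Haenszel odds ratio was 8.95 (95% interval 7.38 to 10.9), so GC accounts for little of it. Within classes of the number of annotated starts it was 8.63 (7.102 to 10.5), and within genes with and without head-to-head neighbours 7.34 (5.94 to 9.06), so neither accounts for most of it. Open chromatin or high transcription at these genes, which may draw signal in many immunoprecipitations, stays open, since no untagged control was analysed here. The design has 1 group, so no biological explanation was tested.

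Summits near tRNA genes could come from their position beside promoters or from reads shared between identical copies. Among the 381 tRNA genes more than 1000 bp from every protein-coding start, 56.4% had a summit within 500 bp, 10.3 times the share of shifted summits, which argues against position. Of 143 tRNA genes whose sequence occurs once, 60 (41.96%) had a summit, with a lower 95% bound of 33.8% against 5.42% for shifted summits. Only identical annotated sequences counted as copies, so near-identical genes that may share reads were not set apart. A summit within 500 bp can also belong to a neighbouring tRNA gene, so this share does not decide on shared reads. Genes with several copies had a higher share (304 of 469, 64.8%, Fisher's exact odds ratio 2.55, p = 1.59e-06), so a contribution of shared reads stays open, as does strong transcription of these genes in any immunoprecipitation. The share was 59.4% on X and 59.5% on the autosomes, and no biological explanation was tested.

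The many peaks around mes-2 could come from a dense run of starts or from extra copies of the region in the tagged line. Among 13140 windows of 40 kb with a number of starts within 20% of the 22 around mes-2, placed every 1 kb and so overlapping, 13 (0.0989%) held as many as 17 summits, with a median of 3, which argues against start density. Extra copies of the whole 40 kb, an explanation narrowed to the whole stretch after its result was seen, would raise summits away from promoters in both replicates: replicate 1 had 6 such summits, a number reached by 2.10% of windows, and replicate 2 had 3, reached by 12.8%, both above the median of 1. The counts decide nothing, as they lie above the median in both replicates but are also reached by 12.8% of windows in replicate 2. Summits near the internal starts of nurf-1 count as promoter peaks, which also limits how many can lie away from promoters here. Extra copies of the whole stretch or of the part from mes-2 onward thus stay open. All 17 summits lie between 14383845 and 14405294 on chromosome II (ce11), so the thresholded summits give no sign of extra copies in the part of the 40 kb before the mes-2 promoter. Neither coverage nor an untagged control was analysed here. No biological explanation was tested.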
